A study of Mus musculus with 2 samples.

How the data were processed

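The data are RNA sequencing counts from 2 samples of mouse Langerhans cells that lack the serotonin 2A receptor gene Htr2a. Per the labels' protocols, ears were digested with dispase, collagenase IV and DNase I, cells positive for CD207 and MHC class II were sorted and treated for 24 hours with imiquimod and an agent labelled a-CD40L, and libraries were made from 10 to 70 ng of total RNA with a stranded low-input total RNA kit. Both samples form 1 group, so no comparison between genotypes or treatments was made. Wild-type and untreated cells were not analysed here. The labels do not say which mice the 2 samples came from. Their sex-linked genes differ, so they are not repeats from a single mouse, but other handling may differ too, and no p-value here reaches beyond these 2 libraries.

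The authors deposited a single table of whole-number counts per Ensembl gene, not normalized, with 1 column per library. The submitters' processing notes name Trimmomatic, HISAT2, SAMtools, StringTie and the genome build GRCm38, without versions. The annotation release, the counting settings, the use of strand and whether a count is a read or a read pair are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The column called library 2 carries the replicate number 2; the other column carries no number and is called library 1. The table held 55487 gene rows, and a last row without an identifier, equal to the column totals, was left out.

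Symbols were matched for 55141 rows, the other 346 rows kept their identifiers, and rows that shared a symbol were summed. Exon lengths (the union of a gene's exons) and positions came from GENCODE M21 on GRCm38, with a length for 55227 rows. Library 1 held 69925160 counts and library 2 42264685, so counting error was small for all but rare genes. Exact 95% Poisson or binomial intervals cover counting error only. They and the exact binomial test between the libraries take each count as independent, which could not be checked. If both reads of a pair were counted, the intervals would be too narrow and the test would call too many genes. A count of 0 allows up to 3 counts, or 0.0429 CPM in library 1 and 0.0710 CPM in library 2.

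Levels are counts scaled to a common library total (CPM), as mean ± SD over the 2 libraries. Before the data were examined, 27 gene lists with 305 distinct genes were fixed (Langerhans cell, MHC class II presentation, mature dendritic cell, IL-12 and IL-23 family, other cytokines, chemokines, interferon-stimulated, NF-κB and CD40 signalling, Toll-like receptors, serotonin receptors, serotonin handling, monocyte and macrophage, conventional dendritic cells of type 1 and type 2, keratinocyte, fibroblast, T cell, B cell, mast cell, neutrophil, melanocyte, endothelial, skeletal muscle, cell cycle, stress response, glycolysis and housekeeping). Relb, Gapdh and Tlr11 each sit in 2 lists. The median log2(CPM + 1) of each list was placed among 10000 random lists of the same size drawn from genes with a count in at least 1 library, as a description of these libraries. Many of these genes are not protein-coding, so the percentile among random lists of protein-coding genes is given beside it where the 2 differ. The list members Mx2, Trac, Trdc, Trbc2, Ighm and Igkc are annotated under other gene types and are left out of that percentile. Because genes that most tissues do not express also carried counts, the 1135 protein-coding olfactory receptor genes were taken, after the data were seen, as a background. A gene was called above background where its CPM per kb of exon exceeded the 95th percentile of these genes in both libraries.

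The 2 libraries were compared with each other to measure how far replicates differ. Genes with at least 1 CPM in at least 1 library were scaled by TMM and tested with the exact binomial test of edgeR 4.0.16 (R 4.3.3), which is the exact test at a dispersion of 0, with Benjamini-Hochberg adjustment at 0.05. For large counts the tool uses a chi-square approximation. This test covers sampling noise alone and compares these 2 libraries, not conditions. No residual degrees of freedom remain for a quasi-likelihood test within 1 group. The biological coefficient of variation was the square root of edgeR's common dispersion with an intercept-only design. Log2 ratios are library 2 over library 1, TMM-scaled with a prior count of 1, and the TMM factors lower a ratio by 0.501 (log2) against total counts, or by less where a library has few counts and the prior count weighs in. The median log2 ratio of each list, over members with a mean of at least 1 CPM, was placed among 10000 random lists matched on mean expression in 10 bins. Simulated data for library 2 against library 1 held sampling noise alone around 1 shared profile, without the further spread of the real libraries. On 27348 genes, the gene test recovered 96 of 100 genes changed by a factor of 2. Of 100 genes changed by a factor of 1.2, 92 were tested and 31 recovered. The 7 false calls hold for such noise and do not carry over to the real libraries. With 26566 genes in the list step, 4 of 100 unchanged lists fell outside the central 95%. Ratios of 2 genes within a library carry exact binomial intervals.

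The genes named followed a rule: Htr2a, a fixed set of cytokines, receptors and markers, the 10 most abundant genes, the 3 most abundant members of each list, the 5 genes with the largest ratio in each direction among those with a mean of at least 10 CPM, and the sex-linked genes Xist and Ddx3y. Some genes that this rule names are not reported here. Other list members named were chosen after their values were seen. Alternatives were other count filters, DESeq2 1.42.0 size factors or total counts in place of TMM, mitochondrial and ribosomal protein genes left out, a dispersion of 0.04, a chi-square test, a prior count of 5, list means, the largest row per symbol, counts per kb, rows without a symbol left out and each library alone. Subtraction of the background and the use of protein-coding genes only were added after seeing the data. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 was used.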

Results

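Gene expression was measured by RNA sequencing in Langerhans cells, the antigen-presenting cells of the epidermis, sorted from ears of mice lacking Htr2a, which encodes the serotonin 2A receptor. The series concerns this receptor, IL-23 and psoriatic inflammation, and its title calls the cells monocyte-derived, while the protocols describe cells sorted from ears. The cells had been exposed for 24 hours to imiquimod, a Toll-like receptor 7 agonist that induces psoriasis-like inflammation in mouse skin, and to an agent labelled a-CD40L. The single group held 2 samples, called library 1 (69925160 counts over 44007 genes) and library 2 (42264685 counts over 48103 genes). All values describe stimulated knockout cells, and none is a difference from wild-type or untreated cells.

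Transcripts of the targeted gene were not detectable above background. Htr2a (ENSMUSG00000034997, protein-coding, GRCm38 chromosome 14, 74640840 to 74709494, plus strand) had 77 counts in library 1 and 117 in library 2. These were 1.10 CPM (95% Poisson interval 0.869 to 1.38) and 2.77 CPM (2.29 to 3.32), or 1.93 ± 1.18 CPM (SD, n = 2). Per kb of its 5606 bp of exon, Htr2a stood at percentile 44.5 of the olfactory receptor genes in library 1 and 33.4 in library 2. Of these 1135 background genes, 94.2% had counts in library 1 and 99.6% in library 2, with medians of 0.221 and 0.645 CPM per kb. The labels do not say which part of the gene was deleted, and a count over the whole gene does not check a partial deletion.

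**Figure D1:**
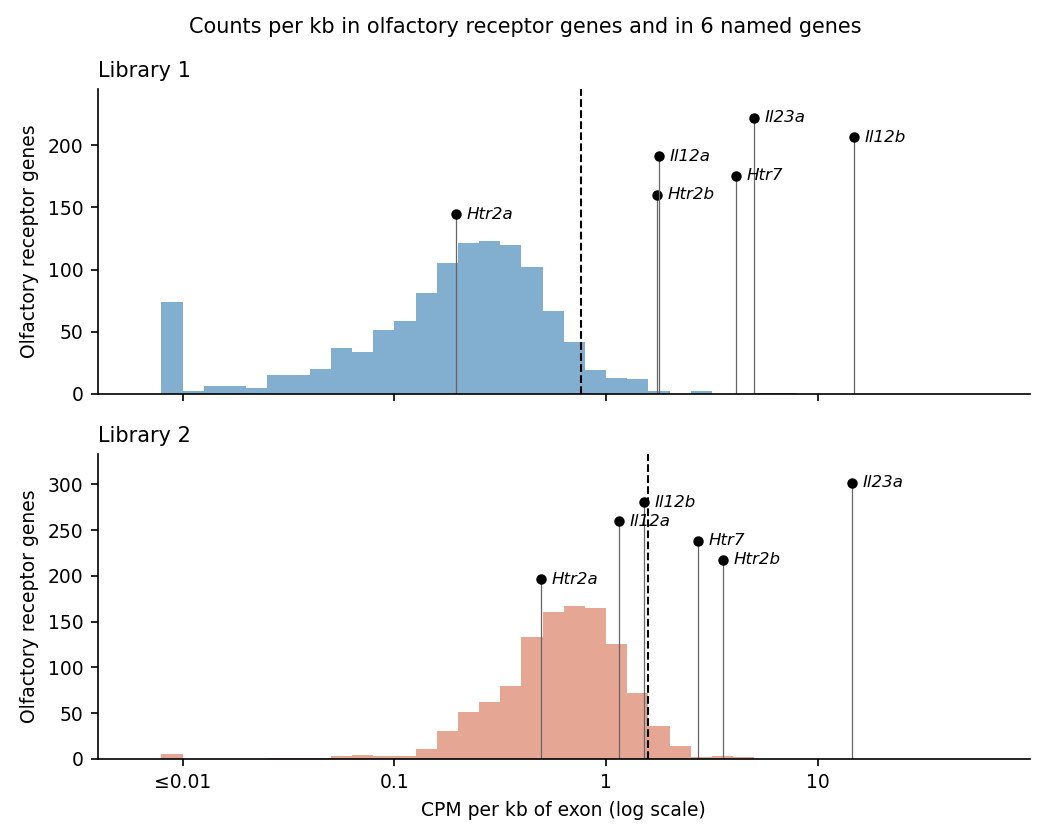
Histograms of CPM per kb of exon (log scale) for 1135 olfactory receptor genes in library 1 (top) and library 2 (bottom), with genes at or below 0.01, including 0, in the leftmost bar, and dots for 6 named genes whose heights carry no meaning. Dashed lines mark the 95th percentile (0.761 and 1.58 CPM per kb); Htr2a lies left of it in both libraries, and Il12a and Il12b do in library 2.

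The cells carried the marker of the sort and high levels of antigen presentation genes. Cd207, which encodes langerin, was at 1089 ± 51.4 CPM (SD, n = 2), and Epcam, an adhesion molecule of Langerhans cells and epithelia, at 167 ± 16.5 CPM. The most abundant Langerhans cell genes were Mfge8, which encodes a bridging protein for apoptotic cells (4161 ± 2889 CPM), Cd207 and the E-cadherin gene Cdh1 (637 ± 221 CPM), and 14 of 14 list members were above background. Of the MHC class II list, 9 of 10 genes were above background, led by the invariant chain gene Cd74 (5627 ± 2207 CPM), H2-Ab1 (2719.5 ± 1085 CPM) and H2-Aa (1658 ± 603 CPM). The medians of both lists lay above those of all 10000 random lists.

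Genes of mature dendritic cells were expressed at levels that differed widely between the libraries. Cd83, a maturation marker, was at 558 ± 313 CPM (SD, n = 2), Ccl22, a T cell chemokine, at 460.5 ± 520.2 CPM, and Fscn1, an actin-bundling protein of mature dendritic cells, at 305 ± 327 CPM. Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 220.1 ± 221 CPM and Cd40 at 80.3 ± 38.5 CPM. Of the list, 12 of 16 genes were above background in both libraries. In the NF-κB and CD40 list 14 of 14 were, led by Tnfaip3, which encodes the NF-κB inhibitor A20 (1490.3 ± 185 CPM), Nfkbia (618 ± 94.6 CPM) and Rel (583 ± 212 CPM). The medians of both lists exceeded those of all random lists.

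Genes of the IL-12 and IL-23 family were expressed at low levels and in a different balance in each library. Il23a, the p19 subunit specific to IL-23, was at 11.2 CPM in library 1 (95% Poisson interval 10.4 to 11.97) and 32.6 CPM in library 2 (30.9 to 34.3). Il12b, the p40 subunit shared by IL-12 and IL-23, was at 29.1 and 2.98 CPM, and Il12a, the p35 subunit of IL-12, at 3.03 and 1.96 CPM. In library 2, Il12b stood at percentile 94.3 and Il12a at percentile 84.8 of background genes per kb, so neither was distinguishable from background there. The ratio of Il23a to Il12a counts was 3.68 (95% interval 3.16 to 4.30) in library 1 and 16.6 (95% interval 13.3 to 20.9) in library 2. The ratio of Il12b to Il23a was 2.61 (95% interval 2.40 to 2.83) in library 1 and 0.0916 (95% interval 0.0757 to 0.110) in library 2, so the order of these genes reversed between the replicates. Il12b counts were 9.58 times those of Il12a in library 1 and 1.52 times in library 2 (95% interval 1.14 to 2.03), where both lay within background. Per kb of exon the ratio in library 2 was 1.31, with an interval that included 1. Besides Il23a, Ebi3, a subunit of IL-27, was above background (10.3 ± 6.61 CPM), which makes 2 of 5 family members in both libraries, against 5 in library 1. The list median stood at percentile 94.8 of random lists, at 96.3 in library 1 and 75.5 in library 2 taken by themselves, and at 66.0 among protein-coding genes.

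Il1b was the most abundant of the other cytokine genes at 1338 ± 452 CPM (SD, n = 2). Il1rn, the natural antagonist of IL-1, followed at 282 ± 0.816 CPM, and Il33, an alarmin of epithelial cells, at 145 ± 178 CPM. Tnf was at 119.9 ± 4.96 CPM, Il10 at 21.6 ± 3.17 CPM and Il6 at 10.6 ± 3.64 CPM, and Il1b counts exceeded those of Il6 206 times in library 1 and 77.1 times in library 2. Of this list 18 of 19 genes were above background, and its median was at percentile 99.99, or 97.3 among protein-coding genes. Of the chemokine genes 14 of 16 were, led by Cxcl16 (626 ± 145 CPM), Cxcl2 (615 ± 171 CPM) and Ccl3 (116 ± 59.4 CPM). Ccl22 counts exceeded those of Ccl17, which binds the same receptor, 48.8 times in library 1 and 9.48 times in library 2, or 10.8 and 2.10 times per kb of exon. Of the interferon-stimulated genes 16 of 18 were above background, among them the antiviral gene Rsad2 (124 ± 96.7 CPM) and the RNA sensor gene Ifih1 (71.6 ± 1.30 CPM). The medians of the chemokine and interferon lists exceeded those of all random lists and stood at percentile 99.97 and 99.8 among protein-coding genes.

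The receptor of imiquimod, Tlr7, was at 14.0 CPM in library 1 and 6.39 CPM in library 2, where it stood at percentile 94.6 of background genes. Tlr9, a receptor for DNA, had more counts than Tlr7 in both libraries, with Tlr7 to Tlr9 ratios of 0.332 (95% interval 0.309 to 0.358) and 0.359 (95% interval 0.311 to 0.413). The most abundant genes of the list were Unc93b1, a chaperone of endosomal Toll-like receptors (76.1 ± 54.2 CPM), Tlr2 (75.1 ± 25.9 CPM) and the adaptor gene Myd88 (61.5 ± 30.9 CPM). Of the list 7 of 15 genes were above background in both libraries and 13 in library 1, and its median was at percentile 99.8, but at 81.1 among protein-coding genes.

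Transcripts of serotonin receptors were scarce, and 2 of 14 were above background: Htr7 at 11.6 ± 3.34 CPM and Htr2b at 5.66 ± 2.77 CPM (SD, n = 2). Htr5a, at 4.43 ± 1.36 CPM, was within background. The ratio of Htr2b to Htr7 counts was 0.265 (95% interval 0.230 to 0.305) in library 1 and 0.826 (95% interval 0.710 to 0.959) in library 2, but per kb of exon it was 1.32 in library 2. Of the genes of serotonin synthesis, transport and breakdown 2 of 8 were above background: Maoa, a monoamine oxidase (29.0 ± 25.8 CPM), and Slc6a4, the serotonin transporter (17.1 ± 12.6 CPM). Slc18a1, a vesicular transporter (5.08 ± 4.09 CPM), and Tph1, an enzyme of serotonin synthesis (4.47 ± 2.34 CPM), were not. The list medians were at percentile 85.2 for receptors and 92.1 for handling genes, but at 6.19 and 36.3 among protein-coding genes, and at 35.5 and 57.7 per kb of exon.

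Genes of other skin and immune cells were measured because a sort can retain them. Keratinocyte genes were abundant: Krt14 was at 3060.4 ± 2468 CPM (SD, n = 2), the desmosome gene Dsp at 2063 ± 1524 CPM and Krt5 at 1981 ± 1524 CPM, and 13 of 14 list members were above background. Krt14 exceeded Cd207 in both libraries, at 1315 against 1125 CPM in library 1 and 4806 against 1052 CPM in library 2. Of the monocyte and macrophage list 13 of 16 genes were above background, among them Itgam (343 ± 259 CPM) and Lyz2 (237 ± 2.42 CPM), and in cells that the series title calls monocyte-derived these are not necessarily genes of other cells. Of the type 1 dendritic cell list 5 of 10 were, led by Irf8 (169 ± 115 CPM), Wdfy4 (43.6 ± 25.2 CPM) and Itgae (39.1 ± 24.2 CPM), and the type 1 markers Xcr1 and Clec9a were not. Of the type 2 list 5 of 8 were, led by Klf4 (266 ± 9.24 CPM), Zeb2 (235 ± 141 CPM) and Irf4 (141 ± 89.3 CPM). Of the T cell list 7 of 12 were, led by Thy1 (49.6 ± 26.5 CPM), Cd3g (40.6 ± 34.6 CPM) and Trdc, the constant region of the γδ T cell receptor (28.9 ± 19.1 CPM). Of the neutrophil list 8 of 8 were, led by S100a9 (304 ± 172 CPM) and S100a8 (115 ± 72.0 CPM), which stressed keratinocytes also express, and Csf3r (35.7 ± 29.0 CPM). The median stood at percentile 99.5 for type 1 and 99.96 for type 2 dendritic cell genes, 99.7 for T cell genes and 99.7 for neutrophil genes, and above all random lists for keratinocyte and for monocyte and macrophage genes. Among protein-coding genes these last 2 still exceeded all random lists, and the others stood at 81.2 (type 1), 98.7 (type 2), 78.7 (T cell) and 89.4 (neutrophil).

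The remaining lists of other cells held few genes above background in both libraries. These were 3 of 10 fibroblast genes, 1 of 7 B cell genes (Ighm, 19.9 ± 18.6 CPM), 2 of 8 mast cell genes (Hdc, 28.1 ± 10.1 CPM, and Kit, 22.7 ± 5.73 CPM), 1 of 8 endothelial genes (Pecam1, 32.2 ± 28.2 CPM), 2 of 8 skeletal muscle genes (Tnni2, 3.16 ± 0.121 CPM, and Mb, 2.52 ± 1.86 CPM) and 0 of 6 melanocyte genes. With each library taken by itself, 8 fibroblast, 4 endothelial, 5 skeletal muscle, 3 mast cell, 2 B cell and 1 melanocyte genes were above background in library 1, against 3, 1, 4, 2, 1 and 1 in library 2. The collagen genes Col3a1 (25.3 ± 23.5 CPM), Col1a1 (22.2 ± 18.9 CPM) and Col1a2 (17.3 ± 11.1 CPM) were above background in library 1 and not in library 2. The list medians were at percentile 99.0 (fibroblast), 77.0 (B cell), 49.96 (mast cell), 92.4 (endothelial), 79.1 (skeletal muscle) and 68.1 (melanocyte). Among protein-coding genes they were at 72.8, 19.3, 1.35, 37.2, 12.2 and 9.57 in the same order, and the fibroblast median was at 91.8 per kb of exon.

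Stress response genes were abundant, with Hspa1a at 3806 ± 3032 CPM, Hspa1b at 3733 ± 2939 CPM and the transcription factor gene Jun at 1318 ± 525 CPM (SD, n = 2). Hspa1a and Hspa1b are near-identical copies, so the division of reads between them is uncertain. All members of the stress (12 of 12), glycolysis (12 of 12), cell cycle (10 of 10) and housekeeping (10 of 10) lists were above background, among them the glycolytic gene Pkm (587 ± 61.7 CPM), the proliferation marker Mki67 (336 ± 48.6 CPM) and Actb (5786 ± 1847 CPM). The cell cycle median was at percentile 99.4, but at 81.3 among protein-coding genes, and the other 3 medians exceeded those of all random lists in both cases.

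**Figure D2:**
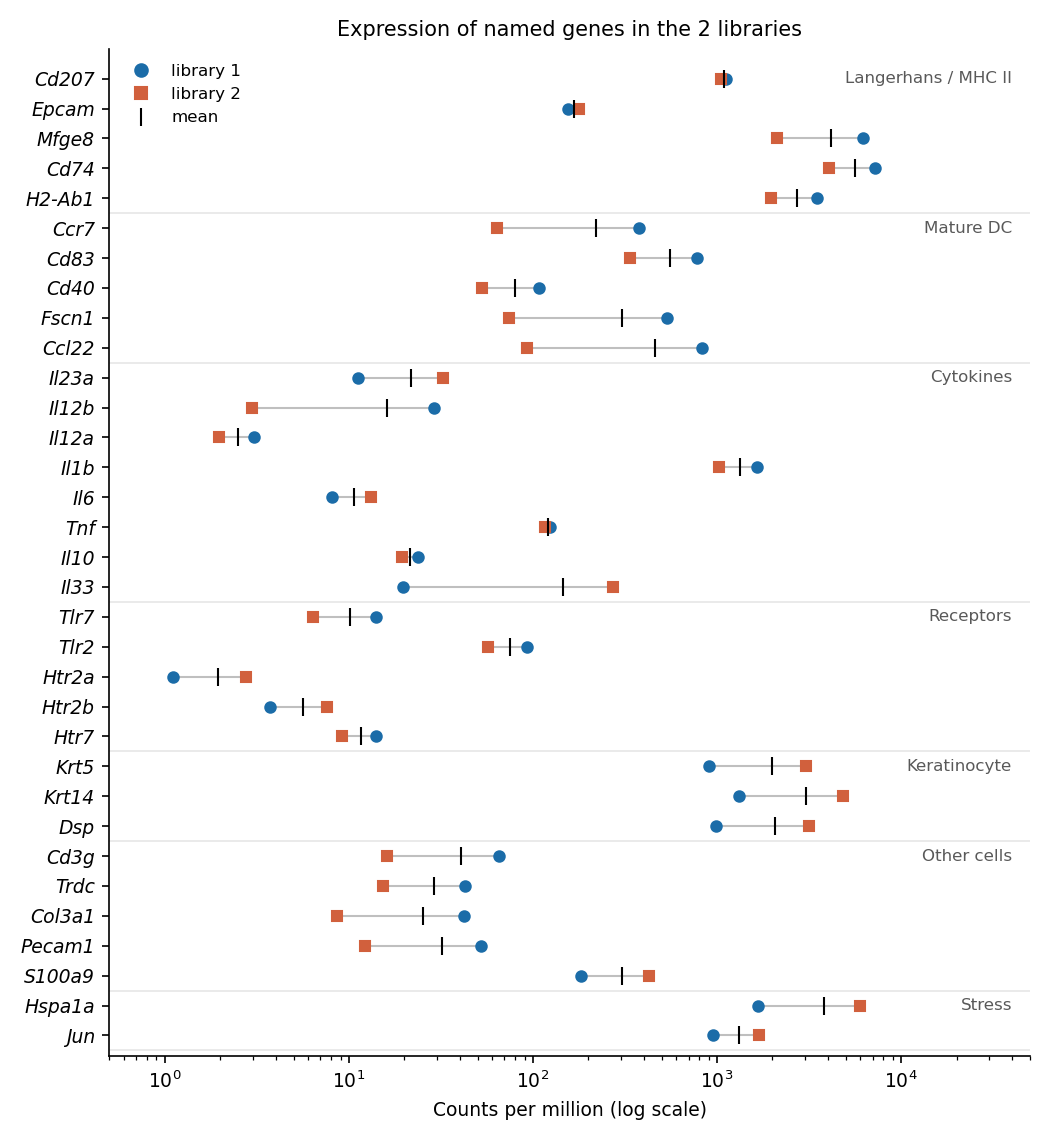
CPM (log scale) of named genes in library 1 (circles) and library 2 (squares), with the mean of both as a tick. Cd207 lies at 1125 and 1052 CPM, whereas Ccl22 (828 and 92.6) and Il12b (29.1 and 2.98) are higher in library 1 and Il23a (11.2 and 32.6) and Krt14 (1315 and 4806) in library 2.

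The 2 replicates differed beyond sampling noise in most tested genes, which include genes within background. Mature dendritic cell and keratinocyte genes differed in opposite directions. The mature dendritic cell list had a median log2 ratio of -2.15, with 15 of 16 genes lower in library 2 and 14 at least 2-fold lower. By CPM, library 1 exceeded library 2 8.94 times for Ccl22, 7.24 times for Fscn1 and 5.92 times for Ccr7. Lamp3, the list member higher in library 2, lay within background in both libraries (percentiles 69.4 and 85.4 of olfactory receptor genes). The keratinocyte list had a median of 1.33, with 11 of 14 genes at least 2-fold higher in library 2. Within the IL-12 and IL-23 family, Il23a had a log2 ratio of 1.04, whereas Il12b was lower in library 2, where it lay within background.

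Across 30356 genes, edgeR's exact binomial test with Benjamini-Hochberg adjustment called 24332 (80.2%), of which 7541 were at least 2-fold higher and 3847 at least 2-fold lower in library 2. These counts were not limited to genes above background, and the background differed too. The median olfactory receptor gene was at 0.658 CPM in library 1 and 1.92 CPM in library 2. Htr2a, which lay within background, was called by the same exact binomial test (adjusted p = 0.000147). An unknown part of the called genes may therefore differ in background alone. Of the called genes 55.2% were higher in library 2 with TMM scaling and 75.9% with total counts alone. The median log2 ratio of all tested genes was 0.15 with TMM and 0.65 with total counts. The log2(CPM + 1) values correlated across genes, which are not independent replicates, with a Pearson r of 0.936 and a Spearman rho of 0.884. The biological coefficient of variation was 0.641. With edgeR's exact test at a dispersion of 0.04, the number was 10189.

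Sex-linked genes differed between the libraries. Xist, the RNA of the inactive X chromosome, was at 3.90 CPM in library 1 and 1384 CPM in library 2, and the Y-linked gene Ddx3y at 149 and 0.0946 CPM. Among genes with a mean of at least 10 CPM, the largest ratios toward library 1 were those of the Y-linked genes Ddx3y, Eif2s3y and Uty and the predicted genes Gm47301 and Gm28036. Of these, Eif2s3y and Gm28036 had 0 counts in library 2. With the same limit on the mean, the largest toward library 2 were those of Xist (7.96), the predicted genes Gm21988 (5.80) and Gm42679 (4.12), Lmo7 (4.64) and Sprr2e (4.36), a gene of the cornified envelope of keratinocytes.

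Of 27 lists, 12 had a median ratio outside the central 95% of matched random lists. By chance 1.35 are expected if the members of a list vary independently of each other. Genes of the same cell type need not, so 12 is not a count of separate shifts. Besides the mature dendritic cell list, 8 were placed low: T cell (median -1.96), B cell (-1.78), Toll-like receptor (-1.56), IL-12 and IL-23 family (-1.49), type 1 dendritic cell (-1.42), monocyte and macrophage (-1.41), MHC class II (-1.33) and Langerhans cell (-1.28). Among Langerhans cell genes Epcam had a log2 ratio of -0.30 with TMM and 0.20 with total counts. Besides the keratinocyte list, the other cytokines (0.30) and stress response (0.24) lists were placed high; Il33 had a log2 ratio of 3.28 and Hspa1a of 1.34, while Il1b had -1.20. These 12 medians had the same sign with DESeq2 size factors and with total counts. The B cell list, with 5 members tested, lay inside the matched range without a count filter (median -0.24) and with at least 10 counts in both libraries (-0.20).

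The other 15 lists lay inside the matched range. Their medians were -0.88 for NF-κB and CD40 genes, -0.76 for interferon-stimulated genes, -0.74 for glycolysis, -0.67 for housekeeping, -0.60 for mast cell, -0.57 for type 2 dendritic cell, -0.40 for endothelial, -0.39 for neutrophil, -0.35 for fibroblast, -0.15 for cell cycle and -0.08 for chemokine genes. They were 0.28 for skeletal muscle, 0.77 for serotonin receptors, 0.80 for serotonin handling and 1.22 for melanocyte genes. Of these 4 lists, 2 of 8, 2 of 14, 2 of 8 and 0 of 6 genes were above background in both libraries. The median background gene was itself higher in library 2 (0.658 and 1.92 CPM), so background may carry part of these positive medians. After background subtraction they were 0.62, 0.63, 1.34 and 1.69. With total counts in place of TMM, the medians were positive for endothelial (0.10), neutrophil (0.11), fibroblast (0.15), cell cycle (0.35) and chemokine genes (0.42).

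**Figure D3:**
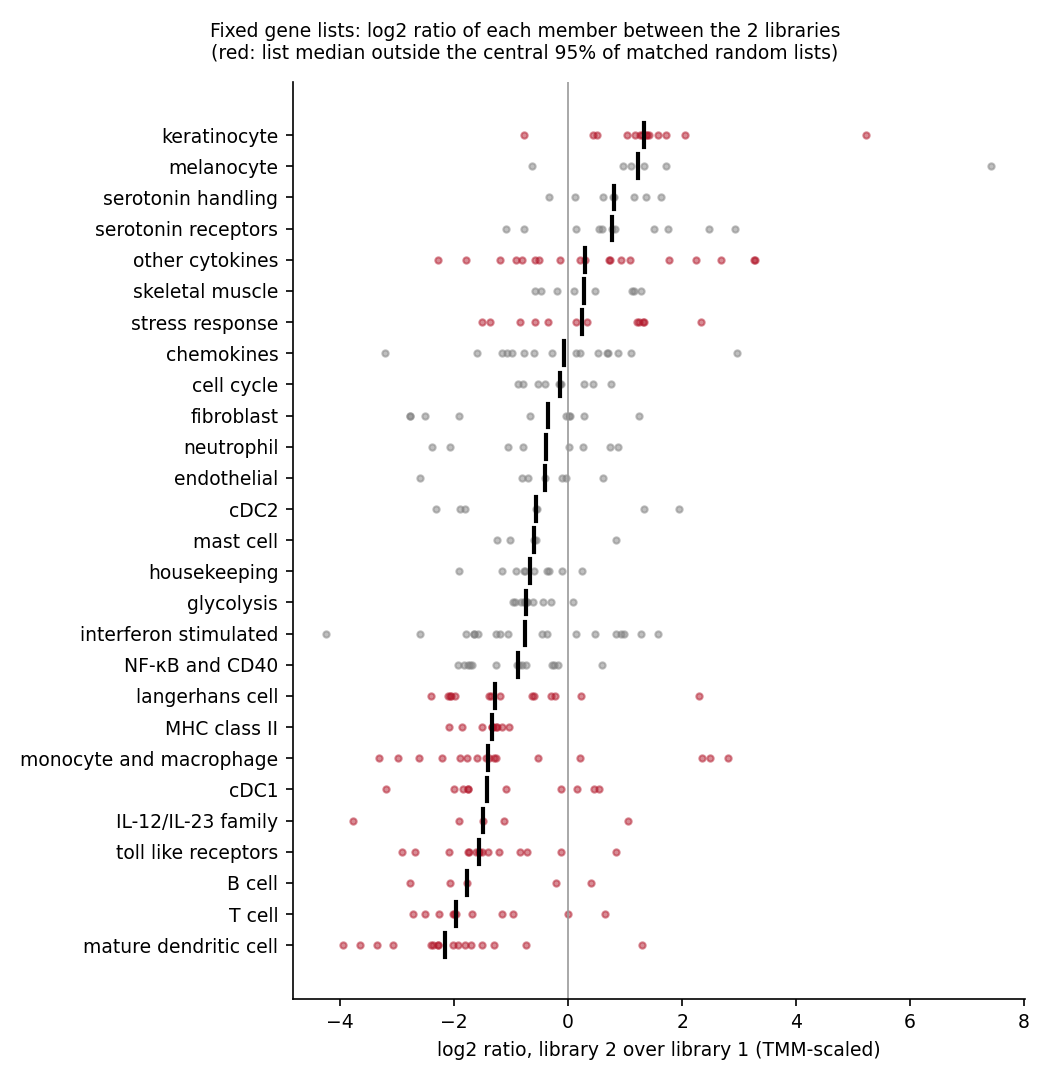
Log2 ratio of library 2 over library 1 (TMM-scaled) for each member (dots) of the 27 gene lists with a mean of at least 1 CPM, with list medians as bars and lists ordered by median. Red lists have medians outside the central 95% of matched random lists, with mature dendritic cell genes lowest (-2.15) and keratinocyte genes highest (1.33); the medians of the endothelial, neutrophil, fibroblast, cell cycle and chemokine lists change sign with total counts in place of TMM.

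The share of counts taken by the most abundant genes was similar in both libraries. The 10 most abundant genes took 22.9% of counts in library 1 and 22.5% in library 2. They were the mitochondrial ribosomal RNA genes mt-Rnr2 and mt-Rnr1, Malat1, the small RNA genes Rn7s1, Rn7s2, Rn7sk and Rpph1, and the genes Gm23935, Gm10800 and CT010467.1, and several have near-identical copies, so their counts are uncertain. The 100 most abundant genes took 37.0% ± 0.0683 (SD, n = 2). Genes of the mitochondrial genome took 11.4% ± 0.594, ribosomal protein genes and their pseudogenes 2.17% and 3.12%, and haemoglobin genes 0.000380%.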

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

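A single identifier without a symbol in the tables used here, ENSMUSG00000118642, held 244011 counts in library 1 and 330646 in library 2, or 0.349% and 0.782% of all counts. It was noticed because it enters no named comparison and took most of the counts of the 346 rows without a symbol.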

How the results depend on the processing

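Background subtraction and the use of protein-coding genes only were chosen after seeing the data. The mean Htr2a level was 2.77 or 1.10 CPM in a single library and 0 after background subtraction. That 0 follows from its place below the background median in both libraries and adds nothing to it. The genes that differ between the libraries numbered 10189 at a dispersion of 0.04, a test that allows more spread, and between 16616 and 34238 under the other alternatives. The biological coefficient of variation was 0.842 without a count filter, 0.478 with at least 10 counts in both libraries, 0.67 without mitochondrial and ribosomal protein genes, 0.634 with DESeq2 size factors, 0.712 with total counts and 0.599 on protein-coding genes; the cause was not tested. The number of lists with a level at or above percentile 95 was 19, and between 13 (protein-coding genes only) and 20 under the alternatives; leaving out the count filter is the same as the main setting there. The number of lists that separate the libraries was 12, and between 11 and 15. Background subtraction brought in the fibroblast (-1.07), endothelial (-1.69) and serotonin handling (1.34) lists, and protein-coding genes the interferon-stimulated list (-0.92). Of 7 ratios within a library, 6 had intervals on the same side of 1 in both libraries, against 4 per kb and 5 after background subtraction. The share of the 10 most abundant genes ranged from 22.5% to 22.9%. Of the list results by setting, 209 of shifts held, 4 were gained and 2 lost, and 212 of levels held and 58 moved. A shift counted as held where its list stayed inside or outside the central 95%, and lists inside it could change sign. A level counted as held where it moved by no more than the SD of the 2 single-library percentiles. That rule is loose where the libraries differ: the B cell level held per kb, at percentile 48.2 against 77.0. Some of these list results could hardly change. DESeq2 size factors and total counts move list members and random lists alike, so the place of a shift among them stays nearly the same. The levels without a count filter repeat the main setting. Low genes were limited by background rather than depth: its 95th percentile in library 2 was 1.58 CPM per kb, and a count of 0 allows 0.0710 CPM. No paired analysis was possible because there is 1 group.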

Other observations

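Some lists held genes that separated in opposite directions; the genes named here were chosen after their values were seen. Among macrophage genes, the scavenger receptor gene Cd163 was at 17.9 CPM in library 1 and 142 CPM in library 2 and Lyve1, a gene of tissue macrophages, at 2.87 and 28.5 CPM, whereas Ccr2, a receptor of monocytes, was at 50.2 and 7.07 CPM and the Fc receptor gene Fcgr1 at 80.7 and 14.4 CPM. Among interferon-stimulated genes, Rsad2 (55.9 and 193 CPM) and Ifit1 (22.8 and 96.6 CPM) were higher in library 2, as was the interferon gene Ifnb1 (1.52 and 13.8 CPM), and Ifit2 (54.3 and 4.02 CPM) and Irf7 (101 and 23.6 CPM) were higher in library 1. Tslp, an epithelial cytokine, was at 4.76 and 64.9 CPM, and the chemokine gene Ccl20 at 6.59 and 73.3 CPM.

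All tests that follow were chosen after the results were seen. Genes silent in most tissues carried counts in both libraries. The tables argue against a difference in depth, since the shallower library 2 had 1.77 times the median olfactory receptor counts per kb of library 1. Genomic DNA in the libraries is a candidate explanation, since DNA of a male holds fewer copies of X than of each autosome and library 1 had Y-linked transcripts: the ratio of X to autosomal median counts per kb of processed pseudogenes was 0.331 in library 1 and 0.789 in library 2, a quotient of 0.42 (95% bootstrap interval over genes 0.323 to 0.546), where DNA predicts about 0.5. This test was first set up on unprocessed pseudogenes and was moved to processed ones after their X median was seen to be 0 in library 1. With an autosomal median of 6.37 counts per kb there, their quotient was 0, which departs from the predicted 0.5. For long intergenic non-coding RNA genes the quotient was 0.361 (95% bootstrap interval over genes 0 to 0.548). Median counts per kb on Y were 5.9 (unprocessed), 9.52 (processed) and 6.47 (non-coding RNA) in library 1 and 0 in library 2. Unspliced RNA was not tested, and no biological explanation was tested.

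Mature dendritic cell genes were lower in library 2, where keratinocyte genes were higher. A smaller share of Langerhans cells as the whole cause predicts equal medians of the mature and MHC class II lists. That holds only where MHC class II genes measure this share whatever the state of the cells, which was not tested. The comparison of these lists therefore cannot decide whether a smaller share is the whole cause. The median log2 ratio of the mature list minus that of the MHC class II list was -0.824 (two-sided permutation over genes, which are not independent, p = 0.0198). Cd207 had a ratio of -0.60, close to the housekeeping median of -0.67, or of -0.10 with total counts. The Langerhans cell list had a median of -1.28. Some of its members fell about as far as the mature list (median -2.15) or further. Among them were Tgfbr1 (-2.41), Spi1 (-2.11), Runx3 (-2.08), Mfge8 (-2.05) and Csf1r (-1.99), whereas 2 of 14 members were higher in library 2. In the MHC class II list, Ctss had a ratio of -2.09, and all 10 members were lower in library 2. The sex of the mice cannot be told apart from the replicate, with 1 library of each sex. A difference in the state of the Langerhans cells stays open and was not tested. A different share of other immune cells was not tested either. The T cell (-1.96), type 1 dendritic cell (-1.42) and monocyte and macrophage (-1.41) lists were also placed low in library 2. The type 2 dendritic cell (-0.57) and neutrophil (-0.39) lists lay inside the matched range.

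Il23a was higher in library 2, 2.92 times in CPM, and Il12b was lower there, at a level within the range of background. The tables argue against genomic DNA as the source of Il23a, which per kb stood at 9.16 times the 95th percentile of olfactory receptor genes in library 2. RNA from keratinocytes, whose most abundant genes Krt14 and Dsp were at 4806 and 3141 CPM there despite the sort for CD207, may carry part of the Il23a counts. That hypothesis cannot be told apart from a change within the Langerhans cells, because the number of keratinocyte-only libraries is 0.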
